A study of Solanum lycopersicum with 4 samples.

How the data were processed

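The series holds 4 libraries of leaves of the dwarf tomato cultivar Micro-Tom, sampled 20 days after inoculation. Per the labels, 14-day-old seedlings received either buffer alone (mock) or sap of tobacco systemically infected with CMV-Fny, a subgroup I strain of cucumber mosaic virus. Each treatment has 1 small RNA library, made from RNA of 18 to 30 nt and sequenced on a HiSeq instrument per the labels, and 1 degradome library. The 2 small RNA libraries were compared. The degradome libraries were not analysed here.

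A single deposited table was used, with 1 line per mature sequence and precursor. Its value columns carry the codes FJL_A and FJL_B, which the sample descriptions give to the mock and the CMV-Fny libraries. The degradome libraries share these codes, and the table was read as small RNA data because it lists miRNA sequences and their hairpins. The raw columns hold estimated counts of reads as the authors deposited them, with reads shared between sequences split into parts, so that 451 mock and 532 CMV values are not whole. The normalized columns hold a signal that, in the deposited table, equals the raw value times 1 constant per library, 1.08 for mock and 0.926 for CMV. The deposited log2 fold change compares the normalized CMV value with the normalized mock value and is infinite where either is 0. The deposited chi-square and Fisher columns hold a p-value per line, and how these were adjusted for multiple tests is not stated per the file headers. The table also gives sequence length, a folding energy index and hairpin positions, which use chromosome names of tomato genome build SL2.40. The aligner, the miRNA caller, their settings and the read minimum for listing are not given in the sources used here. The gene table supplied as reference describes another assembly, SLM_r2.1, so no gene or exon annotation of the precursors was used here.

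The table has 5045 lines and 4747 distinct sequences. Each distinct sequence was counted once, with the listing of most reads; 286 sequences stood on more than 1 line and 26 of them carried different values. Sequence names were taken as the table gives them: sly is tomato, stu potato, nta tobacco, osa rice, ptc the poplar Populus trichocarpa, and PC marks a predicted sequence. Suffixes such as R-1 or 1ss20AG mark variants of the named entry. Of 4251 predicted sequences, 68.4% had more reads than the number in their own name, with a median of 2.0 times that number, and the table does not say why. A sequence was called placed when the table gives a hairpin position on the tomato genome. Of 4554 placed sequences, 3070 (67.4%) occurred in full in their listed hairpin.

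RPM values, reads scaled to the sum of the listed reads, were computed over the distinct sequences. The table holds only part of each library, so its total is not the sequencing depth. Ratios are CMV over mock on the log2 scale with a pseudocount of 0.5 read, and this understates changes of sequences with few reads. Each ratio has a 95% exact conditional binomial interval, with split reads rounded to whole reads, and shares have exact Clopper-Pearson intervals. Intervals of ratios and of read shares, and floors, cover counting error only, since reads from PCR without molecular identifiers are not independent molecules. One read equals 4.38 RPM in mock and 4.14 in CMV. Against a value of 0, a fold is given with a floor of 3 reads in place of the 0. Such a fold is not a confidence limit. For PC-5p-50297_20 it was 73.7, above the lower limit of 59.5 of the exact interval.

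With 1 library per treatment there is no replicate check and no test between conditions, and every ratio compares 2 libraries, not 2 conditions. A rule of size, fixed before the data were examined, replaced a test. A sequence or family was called higher or lower when it differed at least 2-fold, its interval excluded a ratio of 1, and it had at least 10 reads over both libraries. Families are sums over all distinct sequences whose names carry the same miR number, with both arms included. Lists of families were fixed beforehand as RNA silencing components (miR162, miR168, miR403), NLR and immune receptor regulators (miR482, miR2118, miR5300, miR6019, miR6020 and miR6022 to miR6027), and growth and development transcription factors (miR156, miR157, miR159, miR164 to miR166, miR169, miR171, miR172, miR319, miR396). The other lists were auxin signalling (miR160, miR167, miR390, miR393), nutrient and copper (miR395, miR397 to miR399, miR408, miR827, miR857), Solanaceae or tomato restricted (miR1916 to miR1919, miR4376, miR5301 to miR5304), and other moderately conserved families (miR394, miR477, miR529, miR530, miR535). Each list's median ratio has its percentile among 10000 random lists of the same size matched in 5 classes of mean log2 abundance, as a description of these libraries, and a counting interval from 1000 Poisson draws. For hairpins with both arms listed and at least 10 reads on the arms together in each library, the log2 of the less abundant over the more abundant arm was taken per library. Which arm was less abundant was set by the sum over both libraries. Intervals of the median arm difference and of percents of pairs or sequences treat these as independent draws. They describe the spread within these 2 libraries, not between plants, and some arms enter more than 1 pair.

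Sequences named in the text are the 10 highest and the 10 lowest ratios among those with at least 50 reads in the higher library, at most 1 per family and direction, the 5 most abundant of each library, and up to 5 per direction with at least 50 reads in one library and 0 in the other. In each list, the highest, the lowest and the most abundant family are named. Alternatives were the authors' normalized values, median-of-ratios and TMM scaling, totals without the most abundant family, other read minimums, size limits and pseudocounts, every line as listed, only tomato-named sequences and, for families, only exact-named variants. The random lists were also drawn from all families. After the data were seen, alternatives with only placed sequences, with the listings of a sequence added up, and with other sets of arm pairs were added.

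The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The figures used matplotlib 3.10.9, and TMM factors came from edgeR 4.0.16 in R 4.3.3. The calling rule was tested on simulated counts of the 4747 sequences for the CMV over mock comparison, with 200 sequences changed. These were Poisson counts, which hold counting error only, without differences between plants or libraries. The changed sequences were drawn from a range of read counts above the minimum of 10, so the percents called do not cover sequences near it. The rule called 54% of 50 sequences simulated 2 times higher and 48% of 50 simulated 2 times lower. It called 100% of those simulated 4 times higher or lower. Of 693 unchanged sequences with at least 10 reads, 16 (2.31%) were called, which is not a rate of false calls between real libraries. The intervals covered the simulated ratio for 96.5% of 893 sequences. In 200 simulated sets without an arm change, the median arm difference lay between -0.13 and 0.10 and at most 56.7% of pairs were positive.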

Results

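Small RNAs of tomato leaves were compared between 1 mock-inoculated library and 1 library of plants infected with CMV-Fny, 20 days after inoculation, to examine which miRNAs differ in infected plants. The deposited table listed 4747 distinct mature sequences with 228096 reads in the mock library and 241430 in the CMV-Fny library, counting each sequence once. At least 1 read was listed for 3373 sequences in mock and 3861 in CMV-Fny. Reads were concentrated in few sequences. The 10 most abundant sequences held 58.6% of the listed reads in mock and 44.8% in CMV-Fny, whereas 82.6% of the sequences had under 10 reads over both libraries. There were no replicates, so all values come from 1 library per treatment. The intervals of ratios and read shares cover counting error only.

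Sequences of 21 nt made up 68.1% of listed reads in mock (95% Clopper-Pearson interval 67.9 to 68.3%) and 70.9% in CMV-Fny (70.7 to 71.1%). The 22-nt class held 14.8% in mock and 14.0% in CMV-Fny, and the 24-nt class 11.1% (10.9 to 11.2%) and 9.27% (9.15 to 9.39%). The predicted sequence PC-5p-110_5738 alone held 17272 of the 25267.5 reads of 24 nt in mock and 12489 of 22379.2 in CMV-Fny. Whether PC-5p-110_5738 is a miRNA or a fragment of another RNA was not checked. The other reads of 24 nt were more in CMV-Fny than in mock, so the lower share of 24-nt reads rests on that sequence. Counted as distinct sequences rather than reads, the 24-nt class was the most frequent, with 63.2% of the sequences detected in mock and 56.8% of those in CMV-Fny. The share of reads beginning with U was 77.9% in mock (77.8 to 78.1%) and 56.6% in CMV-Fny (56.4 to 56.8%). Reads beginning with A were 12.2% in mock and, by their interval, 23.8 to 24.2% in CMV-Fny. The shares in the same order were, with C, 6.83% and 12.9%, and with G 3.04% and 6.42%. Within the 21-nt class alone, reads beginning with U were 82.0% in mock and 58.9% in CMV-Fny. Counted as distinct sequences, U was the first base of 22.4% in mock and 20.3% in CMV-Fny.

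By the evidence the table gives, sequences on tomato precursors known in miRBase held 45.1% of the mock reads and 54.9% of the CMV-Fny reads. Placed sequences assigned to a precursor of another plant held 32.3% and 24.6%, and predicted sequences 15.9% and 18.3%. Sequences with no position on the tomato genome held 6.66% of mock reads (6.56 to 6.76%) and 2.17% of CMV-Fny reads (2.12 to 2.23%).

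Of the 826 sequences with at least 10 reads over both libraries, 140 were called higher and 75 lower in the infected library, and 611 were neither. The higher calls made up 65.1% of all calls. This split depended on the scaling. It was 101 higher and 99 lower (50.5% higher) with median-of-ratios scaling and 103 higher and 97 lower (51.5%) with TMM, against 126 and 82 with the authors' normalized values. These scalings moved the median log2 ratio of the 826 sequences, 0.36 with the table totals, by -0.37, -0.34 and -0.14. Among 763 placed sequences, 138 were higher and 35 lower. Among 63 sequences without a tomato position, 2 were higher and 40 lower. When the placed sequences alone were used, their own totals included, 126 were higher and 39 lower (76.4% higher). The authors' deposited table gave a Fisher p-value under 0.05 for 406 of its 5045 lines, from its own comparison of the 2 libraries.

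Tomato-named sequences were higher in 17 cases and lower in 4 of 51. Placed sequences named after other plants were higher in 34 and lower in 22 of 122. Predicted sequences were higher in 87 and lower in 9 of 590. The predicted sequences differed by length: of 138 with 21 or 22 nt, 61 were higher and 2 lower with a median log2 ratio of 1.19, while of 389 with 24 nt, 16 were higher and 6 lower with a median of 0.22.

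**Figure D1:**
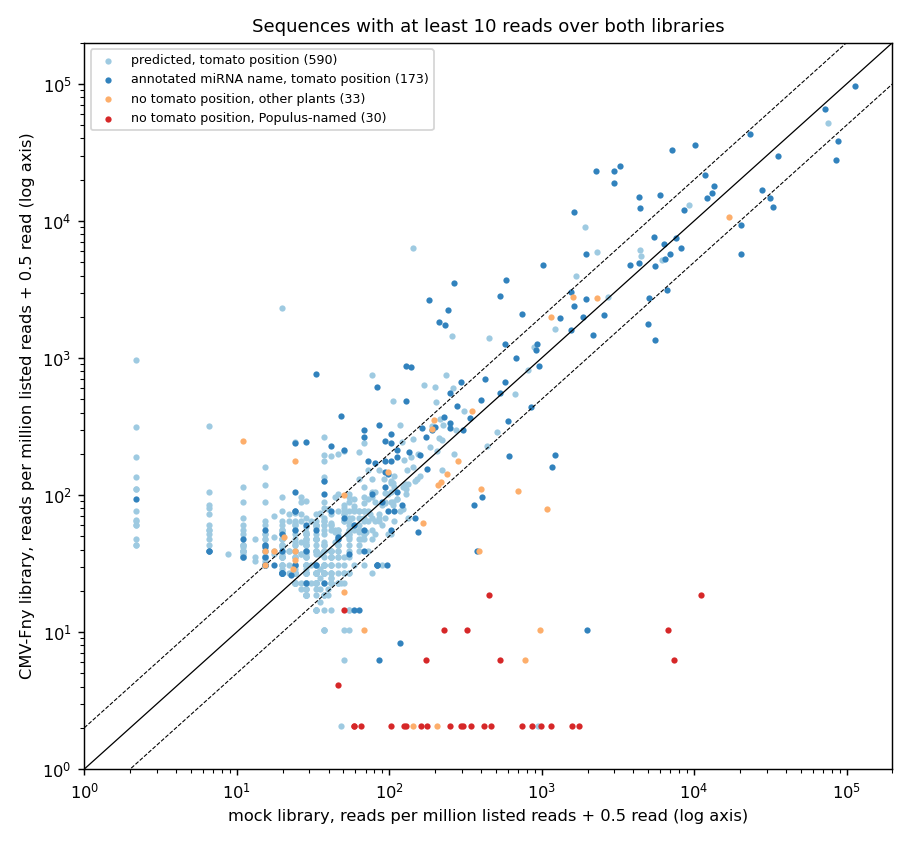
RPM of the listed reads plus 0.5 read in the mock library (x, log axis) and the CMV-Fny library (y, log axis) of the 826 sequences with at least 10 reads, 1 point per sequence; the solid line marks equal values and the dashed lines 2-fold differences. The 30 Populus-named sequences without a tomato position all lie below the lower dashed line, and 590 predicted and 173 annotated sequences with a position spread to both sides.

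The highest ratio among sequences with at least 50 reads in the higher library belonged to the predicted 22-nt sequence PC-5p-50297_20. It had 0 reads in mock and 234 in CMV-Fny (73.7-fold higher against the floor). It lies on a hairpin at chromosome 10, 33488227 to 33488479, minus strand, in SL2.40. The other arm of that hairpin, PC-3p-5715_120, had 4 reads in mock and 556 in CMV-Fny, a log2 ratio of 6.87 (5.67 to 8.92). PC-3p-15196_57 on chromosome 5 had 0 and 75 reads (23.6-fold higher against the floor), and the listed sequence did not occur in full in its hairpin. PC-5p-16296_54 on chromosome 3 had 1 and 77 reads, a log2 ratio of 5.61 with a wide interval of 3.66 to 11.51. PC-5p-941_705 on chromosome 1 (70879746 to 70879857) had 32 and 1540 reads, a log2 ratio of 5.48. Among annotated sequences, the highest were stu-miR393-3p with 7 and 183 reads (log2 ratio 4.53), osa-miR166e-3p_1ss11CA with 2 and 59 (4.49, interval 2.88 to 7.88, no tomato position), sly-MIR6023-p5 with 41 and 643 (3.87), stu-miR6024-5p_R-1_1ss20AG with 60 and 848 (3.73) and sly-miR1919a with 516 and 5613 (3.36, interval 3.23 to 3.49). The signs of these ratios could not change under the scalings tried, which shift all ratios alike, the farthest by -0.37.

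Of the 10 lowest sequences, 9 were Populus-named and without a tomato position. They were ptc-miR1448_L+1R+1 with 1684 reads in mock and 1 in CMV-Fny (log2 ratio -10.22, interval -16.10 to -8.32), ptc-miR1447_1ss14CT with 1548 and 2 (-9.36, interval -12.73 to -7.82) and ptc-miR472b with 2522 and 4 (-9.21). At 0 reads in CMV-Fny were ptc-miR482d-3p with 402 mock reads, ptc-miR6427-3p with 363 and ptc-miR473a-3p with 263. Against the floor these were 142-fold, 128-fold and 92.8-fold lower. Also at 0 were ptc-miR6421-3p with 226, ptc-miR6445a with 197 and ptc-miR1444a_R+1 with 170. The tenth was PC-5p-4654_142, predicted on chromosome 1, with 216 and 0 reads (76.2-fold lower against the floor). Its listed sequence did not occur in full in its hairpin. In all, 13 sequences had at least 50 reads in mock and 0 in CMV-Fny, of which 12 were Populus-named without a tomato position, and 2 sequences had the opposite. The 50 Populus-named sequences without a position summed to 8495.5 reads in mock, 3.72% of listed reads, and 29.5 in CMV-Fny, 0.0122%. The mock library was thus 300-fold higher for this sum (interval 210 to 445), and 47 of the 50 sequences were higher in mock.

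The most abundant sequence of both libraries was sly-miR166a, with 25741 reads in mock and 23493.5 in CMV-Fny (log2 ratio -0.21). Next in mock were sly-miR159 with 20158 and 9183 reads (-1.22, interval -1.25 to -1.18) and stu-miR398a-3p_1ss21GA with 19304 and 6718 (-1.60, interval -1.65 to -1.56), both called lower. The predicted 24-nt sequence PC-5p-110_5738 had 17272 and 12489 reads (-0.55) and nta-miR396a 16568 and 15949 (-0.14). In CMV-Fny, sly-miR162 also ranked among the 5 most abundant, with 5344 and 10399 reads (0.88).

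Of 207 families, 94 had at least 10 reads, and 10 were called higher and 23 lower in the infected library. In 17 of the 23 lower families, over 50% of the mock reads came from sequences without a tomato position. With placed sequences alone, 10 families were higher and 6 lower. With median-of-ratios scaling, 8 families were higher and 32 lower, so that 20.0% of calls were higher against 30.3% with table totals.

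The RNA silencing list, chosen for their targets DCL1, AGO1 and AGO2, had a median log2 ratio of 0.94 (counting interval 0.89 to 0.99) at percentile 90.8 of the random lists. Its mean was -0.89, of the opposite sign, because the sum of miR403-named sequences stood far below the other families. The miR168 family was higher, with 5346.5 reads in mock and 20414 in CMV-Fny (log2 ratio 1.85, interval 1.81 to 1.89), and it was the most abundant of the list by the sum of both libraries. Both arms contributed to it, with sly-miR168a-5p at 1369 and 3766 reads and sly-miR168b-3p at 2304.5 and 8684. The miR162 family was at 0.94, under the size limit, and the miR403-named sequences at -5.47 with 146 and 3 reads. Predicted sequences carry no family name and were left out of this sum. Whether a predicted hairpin is a tomato miR403 precursor was not checked, so the direction of tomato miR403 stays open. Among the unchecked hairpins is that of PC-5p-941_705 (32 and 1540 reads), whose other arm PC-3p-297_2223 was also higher (440 and 2168 reads). Of the miR403 reads in mock, 95.9% lay on sequences without a tomato position, and no family member carried a tomato name. Without such sequences the list's 2 remaining families had a median of 1.33 at percentile 99.4.

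The list of NLR and immune receptor regulators had a median of 0.62 (0.50 to 0.79) at percentile 89.7, with 2 families higher and 7 neither of 9 measured. The miR6023 family was the highest (89 and 1086 reads, log2 ratio 3.52, interval 3.21 to 3.86), and miR6027 was also called higher (1923 and 7467 reads, 1.87). Most of the miR6027 difference lay on the 5' arm, sly-MIR6027-p5, with 680 and 5623 reads (2.96). The other arm, sly-miR6027_R-1, had 1243 and 1844 reads (0.49), under the size limit. The lowest, and by the sum of both libraries the most abundant, was miR482, with 9784 and 6742 reads (-0.62). With only tomato-named sequences, 7 families of the list had a median of 0.02 at percentile 6.08, and the miR6024 and miR6026 families were at -0.18 and -1.07. With only exact-named variants miR6026 was at -0.79. The miR5300 family, at 0.30, changed sign under TMM and median-of-ratios scaling (-0.04 and -0.07).

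Growth and development families had a median of -0.12 (-0.17 to -0.07) at percentile 14.9, with 1 of 10 lower and 9 neither. With placed sequences alone the median was 0.15 and with only tomato-named sequences 0.14. The miR157 family was the lowest (82 and 20 reads, -2.09), miR319 the highest with all sequences (252.8 and 517.5 reads, 0.95) and miR166 the most abundant (34106.5 and 30450 reads, -0.25). Nearly all miR157 reads lay on aly-miR157d-3p_1ss17TC (81.5 and 20 reads). The other arm of its hairpin on chromosome 6 carries a miR156 name, so summing by name split this hairpin between the miR156 and miR157 families. The miR164 family, at 0.00, was negative under the other scalings, down to -0.37. The miR169 family was at -0.98 with all sequences, called lower under 4 of the 5 scalings, and at 0.70 with placed sequences alone. With only exact-named variants miR319 was at 0.09 and miR169 the highest at 1.33, and with only tomato-named sequences miR171 was the highest at 1.82.

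The auxin signalling list had a median of 0.58 (0.46 to 0.70) at percentile 69.4. The miR390 family was higher (524 and 3755 reads, 2.76) and miR393 lower (699 and 235 reads, -1.65), while miR167, the most abundant, was at 0.58 (2792.5 and 4420 reads). The arms of miR393 went opposite ways, with stu-miR393-5p_R-1 at 138 and 46 reads against 7 and 183 for stu-miR393-3p. With only exact-named variants, stu-miR393-3p alone represented the family and its ratio was 4.53.

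Nutrient and copper families had a median of -0.85 (-1.04 to -0.57) at percentile 3.62, with 2 of 6 lower and 4 neither. The lowest was miR395 (100 and 30.5 reads, -1.78), and miR397 was also called lower (7313.5 and 3476.5 reads, -1.15). The most abundant, miR398, was at -0.90 (21233.5 and 12054.5 reads) and was called lower under 3 of the 5 scalings. The miR399 family, at -0.79, was called lower with TMM (-1.13) and median-of-ratios scaling (-1.16), so that 4 of the 6 families were lower under these scalings. With only exact-named variants, which leave out its most abundant sequence, miR398 was at 2.65. The miR827 family, the highest at -0.06, had 93.7% of its mock reads on sequences without a tomato position and was at 3.70 with placed sequences alone.

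Families restricted to Solanaceae or tomato had a median of 0.82 (0.62 to 1.12) at percentile 98.0, with 3 of 8 higher and 5 neither. The miR1919 family was the highest (1016 and 5988 reads, 2.48, interval 2.38 to 2.57), miR5304 was at 2.08 (22 and 100 reads), and miR1918 at 1.25 (10 and 26 reads) was called higher under 3 of the 5 scalings. The lowest, and by the sum of both libraries the most abundant, was miR5301 (8489 and 7975 reads, -0.17). The remaining list, of other moderately conserved families, had 2 measured members and a median of -0.62 (-1.02 to -0.25) at percentile 33.3, with miR530 at -0.99 and miR477 at -0.25, neither called. The miR530 family was called lower under 4 of the 5 scalings.

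When the random lists were drawn from all families, without matching on abundance, the percentiles were 92.0 for RNA silencing, 88.4 for immune receptors, 36.6 for growth, 79.5 for auxin, 14.2 for nutrients, 97.6 for the restricted families and 40.3 for the others. Another scaling shifts every list median alike and leaves its percentile as it was. With median-of-ratios scaling, the scaling that moved them farthest, the medians were 0.57 for RNA silencing, 0.25 for immune receptors, -0.49 for growth, 0.21 for auxin, -1.22 for nutrients, 0.45 for the restricted families and -0.99 for the others.

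The share of a list's mock reads on sequences without a tomato position was 1.93% for RNA silencing, 3.06% for immune receptors, 0.674% for growth, 8.18% for auxin, 0.916% for nutrients, 0.0354% for the restricted families and 5.45% for the others. In CMV-Fny these shares were 0.249, 0.0480, 0.303, 0.261, 0.331, 0.0575 and 0%. Families without any tomato-named sequence numbered 1, 2, 3, 2, 3, 0 and 2 in the same order, and 24-nt sequences 1, 1, 4, 1, 1, 15 and 0.

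**Figure D2:**
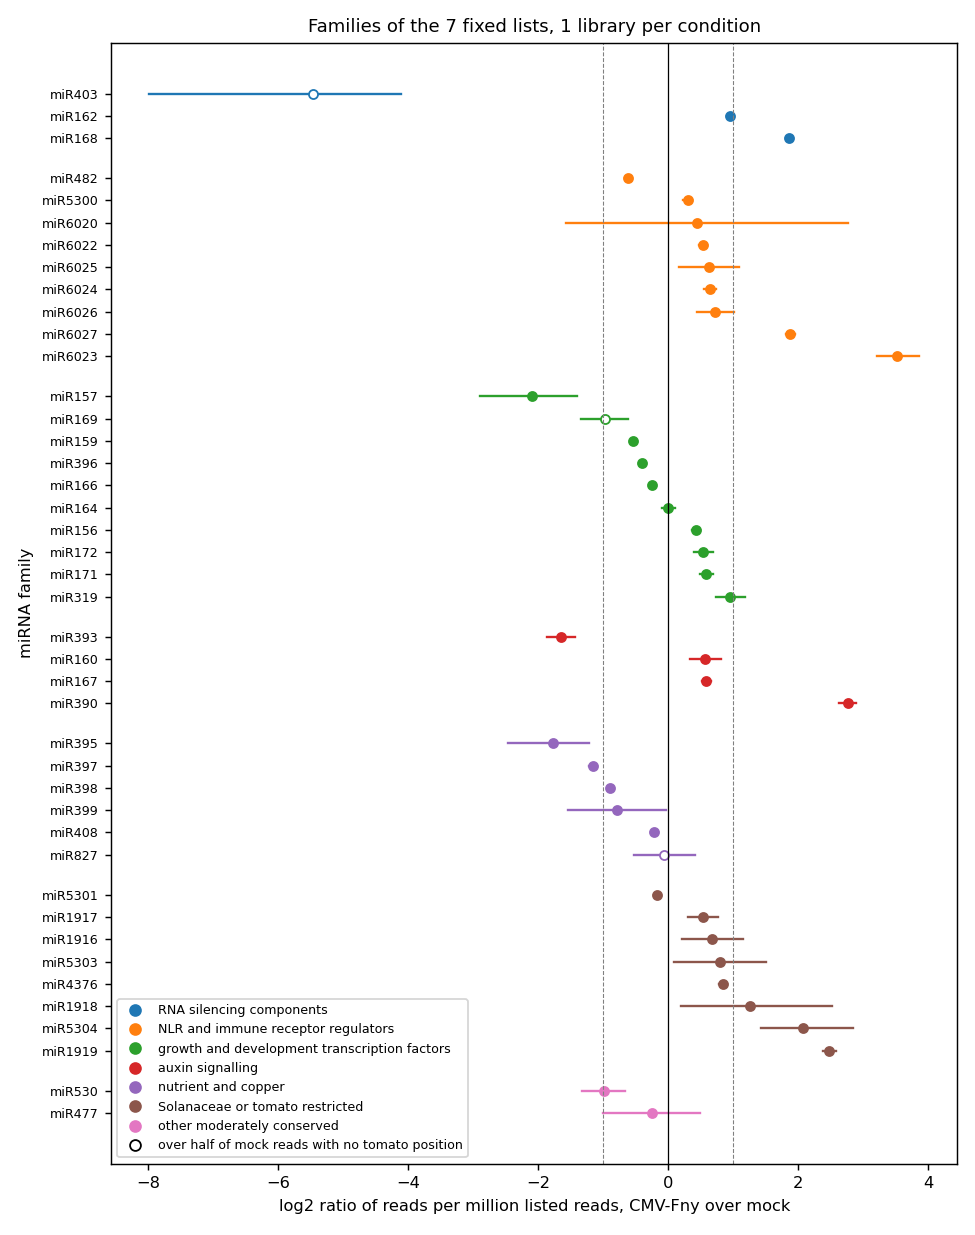
Log2 ratio of RPM of the listed reads, CMV-Fny over mock (x), of each measured family of the 7 fixed lists (y), 1 library per condition; bars are 95% counting intervals, dashed lines mark 2-fold differences, and open points have over 50% of their mock reads on sequences without a tomato position. The miR6023 family is the highest at 3.52 and the sum of miR403-named sequences, without predicted hairpins, the lowest at -5.47. The signs of miR164 and miR5300 flip under other scalings.

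The last comparison asked whether the less abundant arm of a precursor was relatively more frequent in the infected library, since the 2b protein of the virus binds small RNA duplexes. Of 251 pairs of arms, the less abundant arm was relatively higher in CMV-Fny in 155 and lower in 94, with the other pairs equal, or 61.8% higher (55.4 to 67.8%). The median log2 difference, CMV-Fny minus mock, was 0.40 (0.22 to 0.59). Both intervals treat the pairs as independent, although some share an arm, and they do not cover differences between plants or libraries. With 1 pair per more abundant arm, the median was 0.37 in 243 pairs. The relative level of the less abundant arm was at least 2-fold higher in 81 of the 251 pairs and at least 2-fold lower in 40. With a pseudocount of 5 reads the median was 0.08 and 54.2% of pairs were positive. The median was 0.37 in 175 predicted pairs and -0.12 in 15 pairs of the restricted and immune receptor families other than miR482. In the other 61 annotated pairs it was 0.64. The following pairs were chosen after their values were seen. The less abundant arm of sly-miR159 had 743 reads in mock and 6074 in CMV-Fny, which was 3.55% and 39.8% of both arms. That of stu-miR398a-3p_1ss21GA had 680 and 4572 reads, 3.40% and 40.5%, although the more abundant arm did not match its hairpin in full. The partner of sly-miR482b was 0.860% of both arms in mock and 11.8% in CMV-Fny. Counted as lower, the less abundant arm of sly-miR1919a on chromosome 8 (hairpin start 53776381) was 48.9% and 5.99%, sly-miR6026 was 81.4% and 28.5% of its pair, and stu-miR393-5p_R-1 was 95.2% and 20.1%. In mock alone, however, sly-miR6026 and stu-miR393-5p_R-1 were the more abundant arms of their pairs. With roles set in mock, these pairs would count as higher, so their sign depends on how the roles are set. Roles set in mock alone were not tried.

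**Figure D3:**
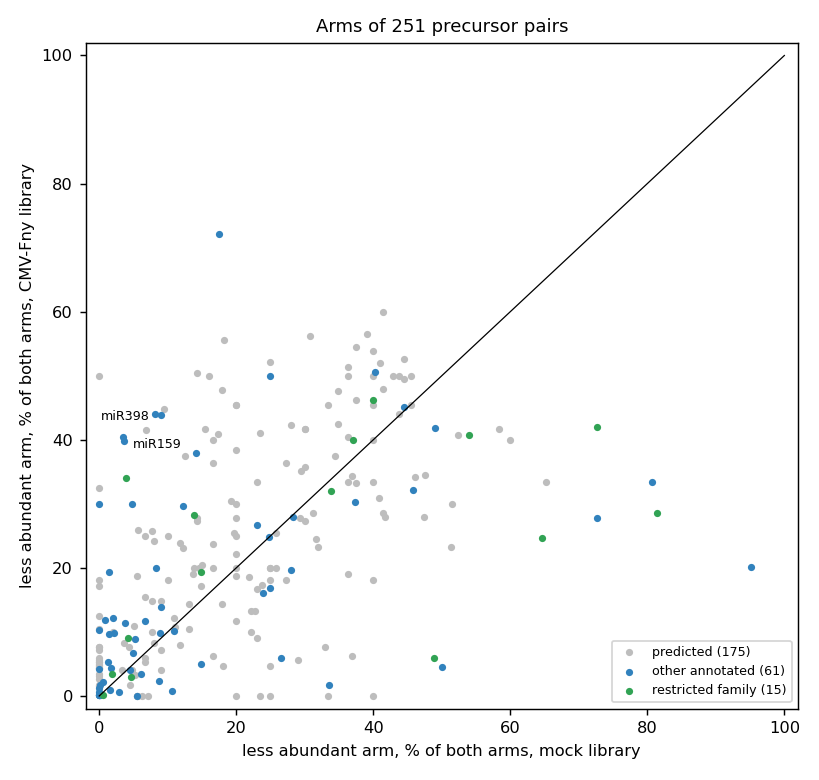
Reads of the less abundant arm as a percentage of both arms in the mock library (x) and the CMV-Fny library (y), for 251 pairs of arms with at least 10 reads per library; the line marks equal shares, and the roles of the arms come from the sum over both libraries. The less abundant arm lay relatively higher in CMV-Fny in 155 pairs, with miR159 at 3.55% and 39.8% and miR398 at 3.40% and 40.5%.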

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

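The alternatives with placed sequences only, with added listings and with other sets of arm pairs were chosen after the results were seen. Of 89 alternative values of summary results, 63 stayed within their interval or within 1.5 times the main count, and 26 moved beyond it.

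A minimum of 50 reads left 71 sequences higher and 43 lower, and a size limit of 4-fold left 82 higher, fewer by construction. With only tomato-named sequences, 15 sequences were higher and 6 lower, and 6 families were higher and 3 lower, since far fewer entered. With placed sequences only, 39 sequences and 6 families were lower, because most lower calls lacked a tomato position. With exact-named variants, 12 families were lower, and miR393 reversed to 4.53 because its 5p variants left the sum. All 140 higher and 75 lower sequences were kept with no minimum, with added listings and with a size limit of 1.5-fold. Under the 4 other scalings all 75 lower calls were kept, and between 101 and 131 of the higher ones.

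One list median lay outside the central 95% of its random lists, the restricted families. With a minimum of 50 reads, and with only tomato-named sequences, 0 lists did. With placed sequences, 2 did, the silencing list at percentile 99.4 and the nutrient and copper list at 0.61. The cause was not tested.

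The 21-nt difference of 2.78 percentage points was 4.20 without the miR166 family, 0.779 in distinct sequences and 3.24 with every line. The 24-nt difference of -1.81 was -2.42 without miR166 and -6.41 in distinct sequences. The first-base U difference of -21.3 was -22.8, -2.16 and -21.0, in the same order as for 21 nt. No sign changed under these alternatives, and distinct sequences weigh rare and abundant ones alike. None of them left out PC-5p-110_5738, on which the lower share of 24-nt reads rests.

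The median arm difference of 0.40 was 0.077 with a pseudocount of 5 reads, where 54.2% of pairs were positive; with a minimum of 2 reads 53.6% were. A larger pseudocount pulls arms with few reads together. With no minimum, 3.08% of predicted and 11.8% of annotated sequences were higher, against 14.7% and 22.5%, since sequences with few reads cannot pass the interval. For named families, 340 alternative values stayed within their interval, 139 moved and 1, of a family called higher or lower, reversed. Counting uncalled families, 20 of these values had another sign, in 9 families: miR398 at 2.65, miR169 at 1.33 and miR6026 at -0.79 with exact-named variants were the largest besides miR393 and miR827 (3.70 with placed sequences) and miR6026 with tomato-named ones (-1.07). For named sequences 203 stayed and 52 moved, and for list medians 59 stayed and 24 moved. The median ratio of the growth list changed sign with placed or tomato-named sequences only (0.15 and 0.14). Depth leaves 82.6% of sequences under 10 reads and out of the calls.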

Other observations

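The tests on the share of the mock excess held by Populus-named sequences, on pairs of arms beyond their own counting error, on predicted hairpins without overlap and on the partner arm of miR397 were chosen after the result was seen.

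The 50 Populus-named sequences without a tomato position had 8495.5 reads in mock and 29.5 in CMV-Fny. Reads of another plant in the mock library and a loss of real tomato miRNAs on infection are candidate explanations. The share of the mock excess that Populus-named sequences and their families held, 77.1% of the sum over unplaced sequences higher in mock and 83.5% of the net excess, cannot separate them, because it restates the pattern and a loss of these sequences would give the same share. A loss on infection would give similar drops among placed sequences. Of 81 placed annotated sequences with at least 50 mock reads, 1.23% (0.0313 to 6.69%) were at least 16-fold lower, between the bounds of 5% and 1%. Nearly all of these placed sequences thus lacked such a drop. With 81 sequences, however, a share under 1% required that none had it, and the interval includes 5%. The test therefore cannot tell the explanations apart. Calls that rest on unplaced sequences, among them 40 of the 75 lower sequences and 17 of the 23 lower families, therefore stay open between them.

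The less abundant arm was relatively higher in the infected library in 61.8% of 251 pairs, with a median difference of 0.40 (0.22 to 0.59). The 200 simulated sets without an arm change, which hold counting error only, reached a median of at most 0.10 and at most 56.7% positive. Counting error alone would put at most about 5% of pairs beyond their own exact interval on the higher side; 12.7% (8.89 to 17.5%) were, so it does not account for these single pairs, but of the 32 higher and 19 lower pairs beyond their intervals 62.7% (48.1 to 75.9%) were higher, which leaves the excess of one direction among them open. How far low read counts shape the size of the difference stays open as well: at a minimum of 100 reads the median was no smaller, 0.46, but its interval (0.01 to 1.20) includes values under 0.20, 0.5 of the main median, and a pseudocount of 5 reads lowered the main median to 0.08. Guide reads of another plant in mock might leave hairpins less shared with other plants unchanged, which was not settled: predicted hairpins, not checked for presence in other plants, and restricted families together had a median of 0.33 (0.18 to 0.53) with 61.1% positive, between the bounds of 0.2 and 0.5, but the 170 predicted pairs overlapping no annotated hairpin outside the restricted families had 0.38 (0.20 to 0.61) and the 15 pairs of restricted families -0.12 (-1.90 to 0.87), with 7 positive and 8 negative. For some pairs, among them that of sly-miR6026 in the restricted families, the roles set by the sum differ from those in mock. Such pairs count as negative only under this choice of roles. An effect of the virus infection could not be tested with 1 library per condition.

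The most abundant guides of miR397, miR398 and miR408 were lower in the infected library, at log2 ratios of -1.10, -1.60 and -1.83. The highest ratio of the 3 guides under any of the 5 scalings was -1.10, below the bound of -0.5. This cannot decide whether scaling of the 2 libraries is the cause of the lower guides. Each of the other scalings lowers all ratios compared with the table totals, and none in the opposite direction was tried. A scaling shifts both arms of a hairpin alike, however. The gap between the miR398 and miR408 guides and their higher partner arms, given next, therefore does not depend on it. For miR398 and miR408, the bound for guide reads of another plant in mock asked only that the partner arms, which differ more between plants, be not lower. The 4 partner arms were higher, between 1.51 and 2.67, and such guide reads alone would leave them unchanged. Guide reads of another plant thus remain a candidate for the lower guides only, not for the higher partner arms. A shift between the arms of tomato precursors would give lower guides and higher partner arms together. Both may apply, and the design cannot tell how far each contributed to the lower guides. The sly-miR159 guide had the same pattern, with log2 ratios of -1.22 for the guide and 2.95 for its partner arm. The same question stays open for it. For miR397 the partner arm was lower as well, at -1.10, but the listed sequence did not match the tomato hairpin in full, so the test cannot say which plant its reads came from.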
